A study of Mus musculus with 6 samples.

How the data were processed

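Single-cell RNA sequencing of endothelial cells from hearts of C57BL/6 wild-type mice was analysed in 6 libraries, 3 from mice aged 3 months and 3 from mice aged 24 months. Per the labels' protocols, tissue was minced and digested with collagenase II and DNase, and cells were enriched with CD31 beads, sorted for CD31 and against GP38 and CD45, and captured with the V2 chemistry of 10x Genomics. The deposited values are whole-number UMI counts per gene and barcode, with no normalization. The submitters' processing notes name bcl2fastq, Cell Ranger, the mm10 assembly, R 3.4.2 and Seurat 2.3.4 without order or settings, and the annotation release and the cell calling are not given in the sources used here. Each library listed 27998 genes. Group and replicate number were taken from the labels, which do not say which animals a library came from, so p-values measure the spread between libraries, which may be technical in part. No 2 libraries agreed within sampling noise (chi-square per degree of freedom 4.86, 5.61 and 10.9 for the pairs of equal replicate number and 13.3 to 21.4 for all other pairs).

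Barcodes with at least 300 genes and at most 20% mitochondrially encoded UMIs were kept. Scrublet, run per library, called 1, 1, 0, 5, 0 and 2 doublets in young replicates 1 to 3 and aged replicates 1 to 3, where 0.8% per 1000 barcodes would give 79, 98, 391, 11, 66 and 601, so its calling did not work, and an alternative removed the expected number by score. Counts were scaled to 10000 UMIs per cell, log-transformed and centred within each library. The 2000 most variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1.0, with 0.6 and 1.5 as alternatives. Clusters were named X-like from fixed marker lists where at least 3 markers were detected in at least 5% of their cells. The list also had to place at least 1 gene, and as many as any list, among the top 10 genes by fold over the other clusters (pseudocount 20 CPM, detected in at least 15% of cells), and to have the highest median fold of its kind. A cluster counted as endothelial where its pan-endothelial marker level reached 50% of the median over clusters. Clusters mixing unrelated cell types were left out. The tools were Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and Scrublet.

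Counts were summed per library over all endothelial cells and over each subtype, and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with DESeq2 1.42.0 as an alternative. Every adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. CPM of single genes use library sizes scaled by TMM, whereas those of marker lists and Ptprc use plain totals. The 24 functional gene lists were tested with camera on voom values of limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry as alternatives. Differences between subtypes were tested with limma on log2 CPM differences within libraries (prior count 1). Shares, depth and variability were compared with exact two-sided permutation tests, and within pairs with exact sign-flip tests, of which that of variability was added after the data were seen. Intervals of shares are exact Clopper-Pearson intervals at 95%, and the limit that a count of 0 allows is 3 counts of the library total.

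The labels number the libraries 1 to 3 in each age group and do not say what a number marks. Pairing a young with an aged library of equal number was therefore inferred from the data. Deviations from the group means correlated between libraries of equal number, with correlations over replicates 1, 2 and 3 of 0.736, 0.693 and 0.631 in all endothelial cells, 0.627, 0.608 and 0.542 in capillary-like, 0.443, 0.478 and 0.388 in arterial-like, 0.213, 0.292 and 0.152 in venous-like, 0.314, 0.308 and 0.28 in endocardial-like and 0.146, 0.234 and 0.169 in lymphatic-like cells, and of −0.553 to 0.019 between libraries of different number. All of the former exceeded 0.1, the level set for using the number as a block, so blocked values are printed where they differ in a call. The correlations and the calls of both fits were computed in the same run.

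Groups, tests, marker and gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes of all endothelial cells were those with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups, up to 12 with the largest fold in each direction, leaving out symbols of predicted genes. Where fewer than 6 passed, the 6 with the smallest unadjusted p were given as values. The rule named 4 per direction in each subtype, up to 4 members of each list, and Pecam1, Cdh5, Ptprc, Pdpn, Cdkn2a, Cdkn1a, Xist and Ddx3y. Its extension to the blocked fit, asking for the same direction in all 3 pairs, was chosen after seeing the data. Also chosen after seeing the data were the final rule for naming clusters, which was changed after its output was seen, the endothelial level, how mixed clusters were recognised, the removal of expected doublets, the clustering without called genes, and the alternatives of the blocked fit. Under the final naming rule a cluster led by Cytl1 was unnamed, and with it endocardial-like cells made up 4.48% ± 1.76 in young and 10.7% ± 9.01 in aged libraries. Some genes that the rule takes are not reported here. Alternatives were computed for the genes and fits named in the text except the blocked values of Cfd and Lcp1, a limit set after the number of values from a wider set was seen. Coordinates are those of a GENCODE annotation of the mm10 assembly.

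The tests were run on simulated counts with the means and sizes of the libraries, 100 genes changed 2-fold and 100 changed 4-fold. In all endothelial cells edgeR recovered 59% and 93% of them (87% and 95% with the block), in capillary-like cells 57% and 98% (80% and 97%), in arterial-like 50% and 94% (71% and 97%), in venous-like 50% and 89% (53% and 90%), in endocardial-like 45% and 88% (64% and 89%), and in lymphatic-like cells 48% and 85% (49% and 78%). In all endothelial cells 9 unchanged genes were called, and 8 with the block. Genes were drawn independently and at the trended dispersion. Real genes vary around that trend and with each other, so recovery in the real data may differ. For a shifted list camera gave an adjusted p of 0.0119 without and 0.152 with the block when the correlation was estimated, so the blocked test with an estimated correlation missed it.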

Results

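Endothelial cells from hearts of wild-type C57BL/6 mice aged 3 months (young) or 24 months (aged) were profiled by droplet-based single-cell RNA sequencing, in which each captured transcript carries a unique molecular identifier (UMI). Cells had been enriched on beads for CD31, the endothelial adhesion molecule encoded by Pecam1. They were then sorted for CD31 and against CD45, the leukocyte antigen encoded by Ptprc. The sort was also against GP38, the product of Pdpn on lymphatic endothelial cells and fibroblasts. Each age group had 3 libraries. Young replicates 1, 2 and 3 held 3165, 3576 and 7107 barcodes with 7060189, 5149783 and 9138568 UMIs. The aged replicates held 1183, 3001 and 8758 barcodes with 1989311, 4675062 and 10809370 UMIs. After filtering, 3013, 3363 and 6682 young and 1083, 2707 and 8249 aged cells were classed as endothelial. The median UMI count per endothelial cell was 1271 ± 345 in young and 1117 ± 147 in aged libraries (SD, n = 3 each, exact two-sided permutation test, p = 0.7). The median number of genes per cell was 794 ± 161 and 721 ± 81.4 (exact p = 0.7), and 666 ± 2.08 and 666 ± 13.1 after thinning each cell to 1000 UMIs (exact p = 1). Thinning left out 242, 1334 and 3257 shallower cells of the young and 436, 974 and 4429 of the aged replicates. With 3 libraries against 3, the smallest p that an exact test can give is 0.1.

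Capillary-like cells were the most numerous endothelial class in both age groups. An exact test of 3 libraries against 3 cannot go under a p of 0.1, so the tests of shares could call no class at 0.05. Capillary-like clusters, led by Car4, Rgcc and Timp4, held 49.3% ± 1.72 of the endothelial cells in young and 48.8% ± 3.11 in aged libraries (SD, n = 3 each, exact p = 0.9). Arterial-like cells, led by Fbln5, Alox12 and Gja4, made up 19.2% ± 2.43 and 16.3% ± 3.84 (exact p = 0.4), and venous-like cells, led by Prss23, Ltc4s and Vwf, 4.48% ± 0.352 and 3.48% ± 1.37 (exact p = 0.4). The venous name rests on 1 listed marker among the top 10 genes, Vcam1, and a median log2 marker fold of 0.91. A further cluster of 340 cells led by Vwf and Prss23 stayed unnamed and is not in that share. Endocardial-like cells, led by H19 and Npr3 with the matrix genes Dcn and Lum, made up 3.99% ± 1.92 and 7.41% ± 4.83 (exact p = 0.3). Lymphatic-like cells, led by Ccl21a, Mmrn1 and Lyve1 and selected against by the GP38 gate, made up 1.16% ± 0.2101 and 2.12% ± 1.68 (exact p = 0.7). A class led by the interferon-induced genes Ifit1 and Ifit3 held 2.84% ± 0.0737 and 3.35% ± 0.699 (exact p = 0.1). An angiogenic class led by Apln, Mycn and Adm held 10.2% ± 1.18 and 7.92% ± 2.32 (exact p = 0.2), and proliferating cells led by Ube2c, Cenpf and Top2a 0.839% ± 0.249 and 1.21% ± 0.361 (exact p = 0.2). Unnamed endothelial clusters, of which one is led by the stress genes Hspa1a and Egr1, held 7.95% ± 1.46 and 9.37% ± 3.27 (exact p = 0.6), and the lowest p adjusted over the classes in these exact tests was 0.6. Within all 3 pairs of equal replicate number the aged library had the lower share of arterial-like and angiogenic cells and the higher share of endocardial-like, interferon and proliferating cells (exact sign-flip p = 0.25 for each, the smallest that 3 pairs can give), although the proliferating shares of pair 1 were 0.83% and 0.831%. Without aged replicate 1 the difference in share, aged minus young, went from −2.81 to −0.693 percentage points for arterial-like, from −2.33 to −1 for angiogenic, from 3.42 to 0.707 for endocardial-like, from 0.513 to 0.1099 for interferon, from 0.367 to 0.555 for proliferating and from −0.999 to −0.459 for venous-like cells. It was −1.42 and −4.44 for arterial-like cells without young replicate 3 and aged replicate 3, and 5.33, 0.195 and −1.77 for endocardial-like, proliferating and venous-like cells without aged replicate 2.

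Some genes that lead these clusters differed with age, so the cells were also clustered without the 178 genes called with age in any class, a step added after the data were seen. That gave 51.8% capillary-like cells in young and 51.4% in aged libraries, 19.2% and 16.1% arterial-like cells. It gave 5.698% and 4.95% venous-like, 5.04% and 10.7% endocardial-like, and 1.16% and 2.05% lymphatic-like cells. Here the venous-like class included a cluster of 138 cells led by Cytl1 and Sfrp1. The cluster led by these genes was unnamed in the first clustering, so the venous-like shares of the 2 clusterings cover different cells. The interferon, angiogenic, proliferating and unnamed classes then held 3.15% and 3.27%, 12.6% and 9.49%, 0.858% and 1.21%, and 0.48% and 0.926%. The exact p of these classes lay between 0.1 and 1. In the first clustering, with all genes, aged replicate 1 stood apart, with 12.8% endocardial-like cells (exact Clopper-Pearson 95% interval 10.9 to 15) and 4.06% lymphatic-like cells (2.97 to 5.42). Without that library the aged mean of the first clustering was 4.695% for endocardial-like and 1.15% for lymphatic-like cells.

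**Figure D1:**
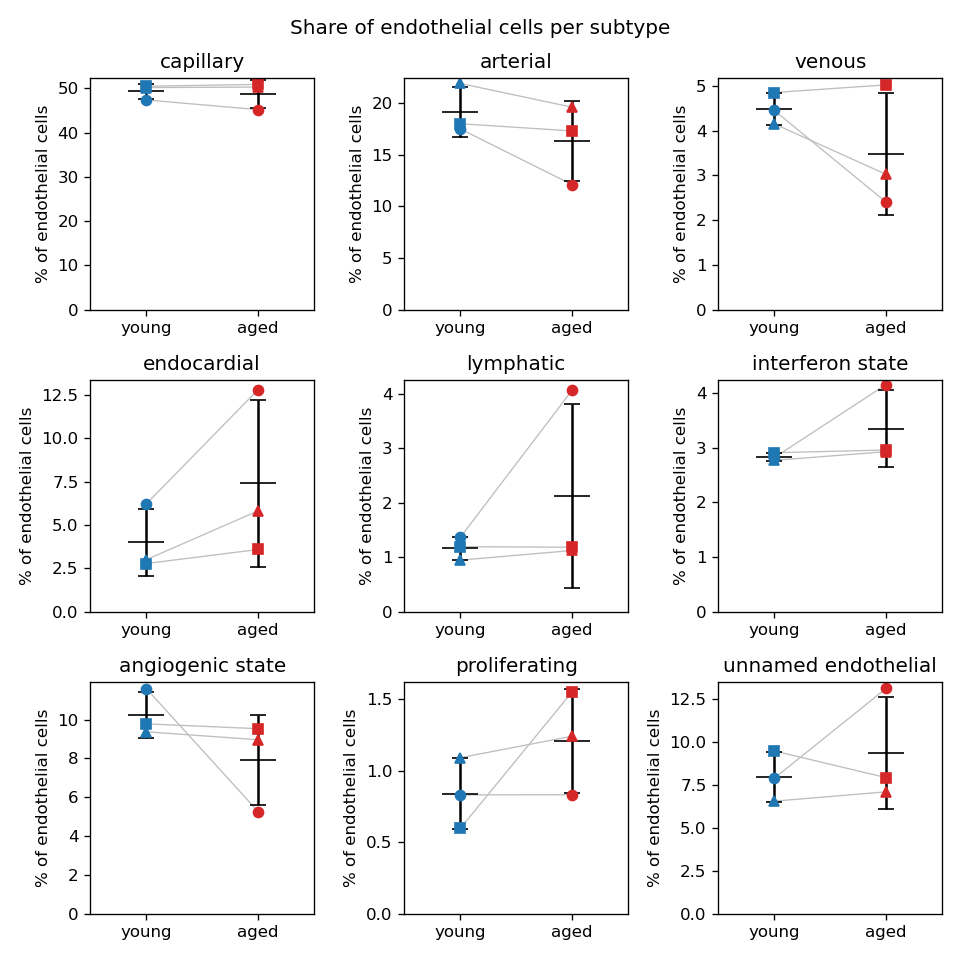
Share of each endothelial class, in percent of the endothelial cells of a library, for 3 young (blue) and 3 aged (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3, grey lines joining equal replicate numbers, and the mean ± SD beside the points. Endocardial-like cells averaged 3.99% in young and 7.41% in aged libraries, with aged replicate 1 at 12.8%.

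Cells of other types were few at both ages. Smooth muscle-like cells made up 2.39% ± 0.144 of all cells in young and 0.859% ± 0.611 in aged libraries (SD, n = 3 each, exact p = 0.1), and B-cell-like cells 0.3904% ± 0.115 and 1.39% ± 0.907 (exact p = 0.2). Macrophage-like cells made up 0.186% ± 0.0369 and 0.407% ± 0.3401 (exact p = 0.4) and fibroblast-like cells 0.0593% ± 0.0289 and 0.137% ± 0.124 (exact p = 0.4). Without aged replicate 2 the aged mean was 0.228% for macrophage-like and 0.0664% for fibroblast-like cells, and without aged replicate 3 it was 0.521% for smooth muscle-like cells. Without aged replicate 1 it was 0.995% for B-cell-like and 0.567% for macrophage-like cells. Clusters mixing endothelial genes with platelet, erythroid or fibroblast genes were left out of the endothelial class and held 0.307% ± 0.0367 and 1.13% ± 0.456 (exact p = 0.1), 0.4896% ± 0.103 and 0.977% ± 0.322 (exact p = 0.1), and 0.432% ± 0.0728 and 0.742% ± 0.337 (exact p = 0.2). In all, 4.25% ± 0.154 of young and 5.63% ± 0.703 of aged cells were not endothelial or were mixed (exact p = 0.1). The lowest adjusted p of these exact tests was 0.2, and the CD45 and GP38 gates act on these shares.

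Markers of other cell types were also summed within the endothelial cells, in CPM, counts scaled to a common library total. The macrophage list stood at 6.01 ± 0.934 CPM in young and 15.1 ± 2.45 in aged libraries (SD, n = 3 each, exact p = 0.1). The platelet list stood at 28.4 ± 2.695 and 51.5 ± 8.86 (exact p = 0.1), and the adipocyte list at 6.55 ± 3.05 and 1.01 ± 0.277 (exact p = 0.1). B-cell markers summed to 0.8997 and 2.18 CPM (exact p = 0.2), neutrophil markers to 1.595 and 6.06 (exact p = 0.2), the latter with 12.7 CPM in aged replicate 1 against 2.72 and 2.81 in aged replicates 2 and 3. T or NK markers summed to 4.24 and 4.77 (exact p = 0.6), fibroblast markers to 347 and 570.3 (exact p = 0.2), and pericyte markers, Rgs5 among them, to 114 and 86.3 (exact p = 0.2). Cardiomyocyte, smooth muscle, erythroid, epicardial and Schwann cell markers summed to 230.2 and 237, 62.5 and 62.6, 204 and 293, 75.5 and 80.6, and 37.2 and 39.6 CPM (exact p from 0.6 to 1). The erythroid sum of aged replicate 2 was 554 CPM, against 91.3 and 234 in aged replicates 1 and 3. Pan-endothelial markers summed to 8468 and 8690 CPM (exact p = 0.7). Those of the endothelial classes summed, young against aged, to 28180 and 25790 CPM for capillary, 1520 and 1680 for arterial, 1064 and 1415 for venous, 514 and 702 for endocardial, and 642 and 1077 for lymphatic cells. Interferon, angiogenic and proliferating markers summed to 952 and 1247, 1285 and 1220, and 793 and 758 CPM, and the exact p of the class lists ranged from 0.1 to 0.9.

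The central comparison asked which transcripts differ between endothelial cells of young and aged hearts, with counts summed over all endothelial cells of a library. Aged cells held more RNA of Csprs, of 3 Serpina1 genes, of the lectin-like receptor gene Klra9 and of Cystm1. Csprs, on the unplaced scaffold GL456221.1 of the mm10 assembly (111572 to 163011), rose from 7.75 ± 2.19 to 78.5 ± 35.1 CPM (SD, n = 3 each, log2 fold change 3.299, SE 0.38, adjusted p = 0.0463). Serpina1b, Serpina1d and Serpina1e encode forms of the protease inhibitor alpha-1-antitrypsin and lie on chromosome 12 (103728156 to 103830373, 103763594 to 103773592 and 103946931 to 103958975). Serpina1e rose from 2.4 ± 1.18 to 21.6 ± 7.82 CPM (log2 3.15, SE 0.42, adjusted p = 0.0463). Serpina1b rose from 1.41 ± 0.32 to 17.5 ± 4.65 (3.62, SE 0.32, 0.00381) and Serpina1d from 0.92 ± 0.37 to 15.1 ± 4.45 (3.86, SE 0.36, 0.00381). Klra9 (chromosome 6, 130178675 to 130193112) rose from 38.9 ± 1.91 to 105 ± 19.3 CPM (1.44, SE 0.16, 0.00937). Cystm1 (chromosome 18, 36342520 to 36403097) rose from 29.7 ± 2.23 to 60.5 ± 6.83 (1.03, SE 0.14, 0.0463). Csprs, the Serpina1 genes and Klra9 belong to families of near-identical copies among which reads can be split, so their single values are uncertain. In edgeR's quasi-likelihood test 7 of 11251 genes were higher and 0 lower in aged cells. In all, 422 had an unadjusted p under 0.05 in that test, fewer than chance alone would give. DESeq2's Wald test called 31 higher and 3 lower. Lower values that did not pass without the block were those of Rgs5 (log2 −0.87, adjusted p = 0.115), Akap5 (−0.88, 0.19), the adipocyte marker Cfd (−3.44, 0.208), Chst7 (−0.69, 0.458), Lcp1 (−1.23, 0.512) and Timp4 (−0.73, 0.648). With the replicate number as a block Cfd (adjusted p = 0.0246) and Lcp1 (0.0345) passed as lower, as did the other 4, whose values follow. No alternatives were computed for the blocked values of Cfd and Lcp1. The values of 997 genes did not overlap between the groups, 8.86% of those tested, where chance gives 10%. The count was 3, 3, 2 and 3 without young replicates 1, 2 and 3 and aged replicate 2. The adjusted p of Csprs was 0.108, 0.71, 0.339 and 0.249 without young replicates 1, 2 and 3 and aged replicate 2, and that of Serpina1e 0.0678, 0.399, 0.216, 0.0864 and 0.177 without young replicates 1, 2 and 3 and aged replicates 1 and 2. That of Klra9 was 0.05 and 0.149 without young replicates 1 and 3 and that of Cystm1 0.0806 to 0.216 without any 1 library. In these same fits the log2 fold change was 3.15 to 3.56 for Csprs and 2.775 to 3.61 for Serpina1e. It was 1.395 to 1.46 for Klra9 and 0.927 to 1.098 for Cystm1. The folds thus stayed near those of all 6 libraries where the calls were lost. Over all alternatives the highest adjusted p was 0.71 for Csprs, 0.399 for Serpina1e, 0.149 for Klra9, 0.311 for Cystm1, 0.376 for Serpina1b (with equal cell numbers) and 0.0469 for Serpina1d.

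**Figure D2:**
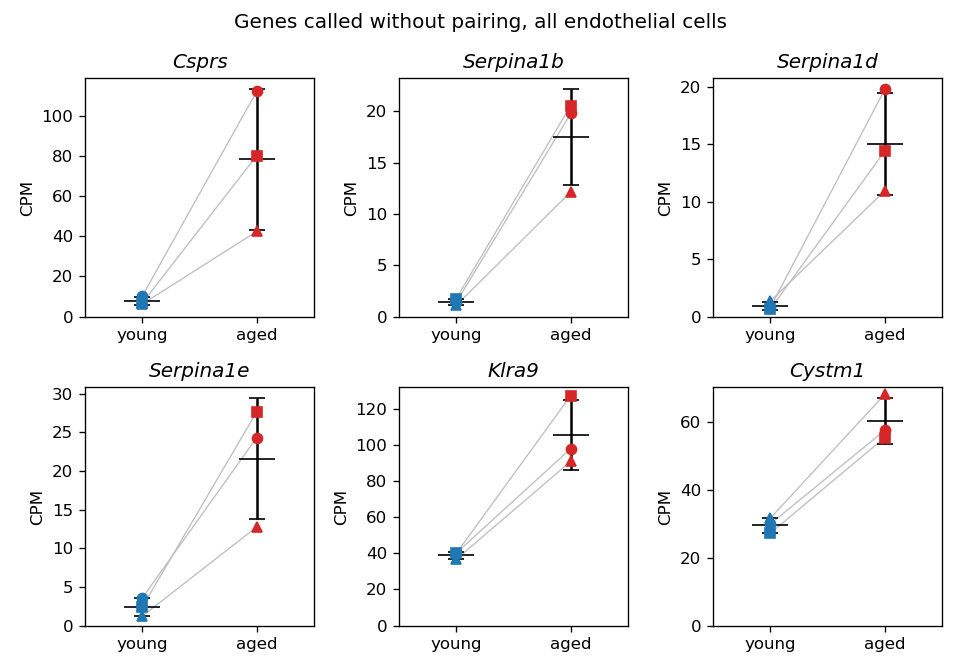
CPM in all endothelial cells for 6 genes that rose with age, for 3 young (blue) and 3 aged (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3, grey lines joining equal replicate numbers, and the mean ± SD beside the points. Csprs averaged 7.75 CPM in young and 78.5 CPM in aged libraries, and Klra9 averaged 38.9 and 105 CPM.

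Genes of the sort, of senescence and of the sex chromosomes did not pass the test in all endothelial cells. Pecam1 was at 851 ± 65.3 CPM in young and 918 ± 84.7 in aged libraries, Cdh5, which encodes VE-cadherin, at 1012 ± 71.7 and 982 ± 80.97, and Pdpn at 4.41 ± 2.25 and 6.5 ± 5.33 (SD, n = 3 each, edgeR log2 fold changes 0.11, −0.043 and 0.32, each with an adjusted p of 0.999). The log2 fold change of Pdpn in all endothelial cells was −0.24 without aged replicate 1, and the log2 fold change of Cdh5 in all endothelial cells was 0.015 without aged replicate 3. Ptprc was at 0.103 and 0.116 CPM. Cdkn2a, which encodes the cell cycle inhibitor p16, was at 1.42 ± 0.4 and 3.74 ± 0.65 CPM (log2 1.34, adjusted p = 0.772, and 0.148 with the replicate number as a block), and Cdkn1a, which encodes p21, at 501 ± 192 and 389 ± 32.1 (−0.36, 0.999). The Y-linked gene Ddx3y was at 78.5 ± 16.8 and 79.8 ± 6.96 CPM (log2 0.018, adjusted p = 0.999), and its log2 fold change in all endothelial cells was −0.070, −0.070 and −0.041 without young replicates 2 and 3 and aged replicate 1. The Y-linked list of 4 genes summed to 144 and 151 CPM (exact p = 1). Xist, from the inactive X chromosome of females, had 0 counts in every library except aged replicate 3, which had 1, and a count of 0 allows up to 1.65 CPM in aged replicate 1, the library with the smallest total.

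With the replicate number of the labels as a block, aged endothelial cells held more RNA of Ubd and of antigen presentation genes, and less of heat shock genes and of the water channel gene Aqp1. Ubd, a ubiquitin-like gene induced by inflammatory cytokines (chromosome 17, 37193892 to 37196095), rose from 1.65 ± 1.41 to 27.3 ± 12.6 CPM (SD, n = 3 each, paired log2 fold change 4.13, SE 0.25, adjusted p = 1.80e-05, and 0.0739 without the block). Csprs, Serpina1e and Klra9 rose in this fit too (adjusted p = 2.83e-06, 4.86e-05 and 5.05e-05), as did the complement gene Cfb (log2 1.73, 0.016), the nucleic acid sensor gene Zbp1 (1.696, 0.00335) and Spock2 (1.42, 0.00309). Rgs5, a regulator of G-protein signalling also used as a pericyte marker (chromosome 1, 169655501 to 169695813), fell from 74.6 ± 8.8 to 41.1 ± 4.12 CPM (paired log2 −0.85, SE 0.096, adjusted p = 0.00136). Aqp1 (chromosome 6, 55336432 to 55348555) fell from 2619 ± 515 to 1595 ± 273 (−0.71, SE 0.11, 0.0144). The cell cycle inhibitor gene Cdkn1c fell from 648 ± 95.7 to 398 ± 95.5 CPM (−0.72, 0.00299) and the metalloproteinase inhibitor gene Timp4 from 472 ± 41.96 to 283 ± 70.8 (−0.75, 0.00386). The glucocorticoid-induced gene Tsc22d3 fell from 194 ± 71.3 to 115 ± 37.3 (−0.74, 8.61e-04), and Rsrp1 from 820.2 ± 326 to 491 ± 267 (−0.802, 0.00252). Akap5 (−0.896, 0.0177), Chst7 (−0.71, 0.0246), Lurap1l (−0.66, 0.0246) and Rhob (−0.59, 0.0218) fell as well. The blocked test called 83 genes higher and 26 lower, including all 7 calls made without the block. With it, 1263 of 11251 genes had an unadjusted p under 0.05, more than chance alone would give. DESeq2's blocked Wald test called 50 higher and 16 lower. The blocked count was 51 without replicate 1 and 228 without replicate 2. The blocked adjusted p was 0.0637 without replicate 1 for Zbp1 and 0.0785 without replicate 1 for Rhob. It was 0.0999 and 0.0678 without replicates 1 and 3 for Akap5, 0.107 and 0.188 without replicates 1 and 3 for Chst7 and 0.0637 and 0.179 without replicates 1 and 3 for Lurap1l. Over all alternatives the highest was 0.0637, 0.0785, 0.147, 0.416 and 0.255 for these genes. The blocked calls of Cfb and Spock2 were lost with equal cell numbers (adjusted p = 0.21 and 0.0612, the highest over their alternatives) and that of Rgs5 when all barcodes were summed (0.42, likewise the highest). The paired log2 change of Rgs5 was then −1.74, a larger fall. That sum holds the smooth muscle-like cells, which Rgs5 also leads and whose mean share was lower in aged libraries. Whether RNA of such cells moved Rgs5 in the endothelial cells was not tested.

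Of the 24 gene lists, the one for antigen presentation by MHC class II had the largest median change. Of its 8 genes 6 were measured, and all of these rose with the replicate number as a block. Cd74, which encodes the invariant chain (chromosome 18, 60803848 to 60812652), rose from 17.3 ± 6.51 CPM in young to 129 ± 113 in aged libraries (SD, n = 3 each, paired log2 2.67, SE 0.29, adjusted p = 0.0404). H2-Aa and H2-Ab1, which encode the chains of the class II molecule I-A (chromosome 17, 34282744 to 34287823 and 34257689 to 34269419), rose from 9.51 ± 3.15 to 47.5 ± 27.6 CPM (2.19, 7.37e-04) and from 14.8 ± 3.61 to 63.9 ± 32.9 (2.01, 1.74e-04). H2-Eb1 (1.95, 0.00331) and the peptide-loading genes H2-DMa (1.67, 0.0345) and H2-DMb1 (1.96, 0.00127) also rose. Aged replicate 1 stood apart, with Cd74 at 259.5 CPM against 71.9 and 56.9 in aged replicates 2 and 3, H2-Aa at 79.2 against 28.6 and 34.7, H2-Eb1 at 42.4 against 10.2 and 16.3 and H2-DMa at 19.8 against 7.8 and 7.83. Without pair 1 the paired log2 change was 2.21, 1.88, 1.76, 1.52, 1.21 and 1.79 for Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and H2-DMb1. Camera with a preset correlation called the list higher (median log2 1.998, adjusted p = 7.25e-16, and 2.78e-16 with the block). The call was lost with an estimated correlation (adjusted p = 0.513 without and 0.596 with the block). Without the block edgeR called 0 of the genes over all genes tested (422 of all genes at an unadjusted p under 0.05), and 6 rose when adjusted over the list alone, as 6 did with the block. Of the 10 splits of the 6 libraries into 3 and 3, 9, the split by age among them, had at least as many lists called by the preset correlation as the 6 of the split by age, and so did 4 of 4 with the block. In the same cells the macrophage markers were at 6.01 and 15.1 CPM and the B-cell markers at 0.8997 and 2.18 CPM. The blocked adjusted p was 0.43 without replicate 2 for Cd74 and 0.209 without replicate 1 for H2-DMa, and with equal cell numbers it was 0.621, 0.41, 0.544, 0.58 and 0.102 for Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa. With all barcodes summed it was 0.35, 0.112 and 0.144 for Cd74, H2-Aa and H2-DMa. The highest over all alternatives was 0.621, 0.41, 0.544, 0.58 and 0.209 for these genes and 0.0286 for H2-DMb1.

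**Figure D3:**
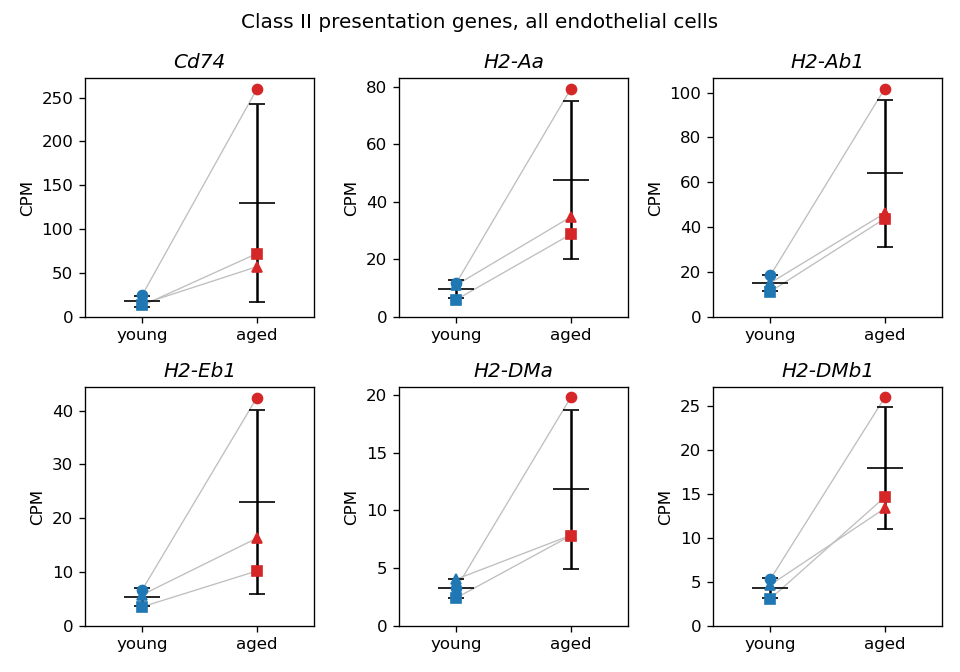
CPM of MHC class II presentation genes in all endothelial cells, for 3 young (blue) and 3 aged (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3, grey lines joining equal replicate numbers, and the mean ± SD beside the points. Cd74 averaged 17.3 CPM in young and 129 CPM in aged libraries, and H2-Ab1 averaged 14.8 and 63.9 CPM.

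The heat shock list, made of protein-folding chaperone genes, was lower in aged cells. Of its 15 genes, 5 fell with the replicate number as a block and 9 did so when adjusted over the list alone. Hspa1a, which encodes the inducible HSP70 (chromosome 17, 34969190 to 34972156), fell from 1299.7 ± 622 to 746 ± 324 CPM (SD, n = 3 each, paired log2 −0.801, SE 0.094, adjusted p = 0.00181), and its neighbour Hspa1b (34956436 to 34959238) from 64.3 ± 20.9 to 41.04 ± 15.1 (−0.64, SE 0.11, 0.0218). Hsp90aa1 (−0.499, 0.0218), Hspb1 (−0.51, 0.0151) and Hspa8 (−0.48, 0.0247) also fell, and Hsp90ab1 (−0.37, 0.129) did not pass. Camera with a preset correlation called the list lower (median log2 −0.38, adjusted p = 6.98e-08, and 6.67e-13 with the block). The call was lost with an estimated correlation (adjusted p = 0.807 without and 0.596 with the block). Without the block edgeR called 0 of these genes, both over all genes tested (422 of all genes at an unadjusted p under 0.05) and adjusted over the list alone. The blocked adjusted p was 0.169 without replicate 1 for Hspa1b, 0.0975 without replicate 1 for Hsp90aa1, 0.0999 and 0.0544 without replicates 1 and 2 for Hspa8 and 0.077 without replicate 1 for Hspb1. Over all alternatives the highest was 0.169, 0.0975, 0.0999 and 0.077 for these genes and 0.00656 for Hspa1a.

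**Figure D4:**
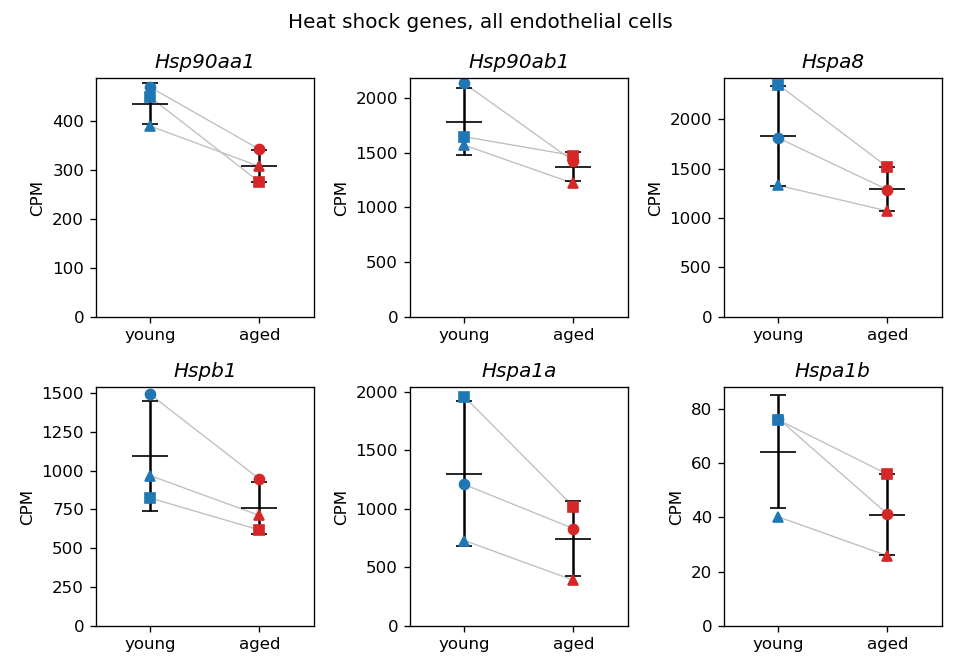
CPM of heat shock genes in all endothelial cells, for 3 young (blue) and 3 aged (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3, grey lines joining equal replicate numbers, and the mean ± SD beside the points. Hspa1a averaged 1299.7 CPM in young and 746 CPM in aged libraries and was lower in the aged library of each pair.

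Nuclear genes of oxidative phosphorylation were slightly lower in aged cells as a list, and lists of class I presentation, type I interferon response and coagulation were higher. The 57 oxidative phosphorylation genes had a median log2 fold change of −0.105 (camera adjusted p = 6.20e-06, 7.55e-09 with the block, and adjusted p = 0.948 and 0.903 with an estimated correlation). No member passed by edgeR in either fit, nor adjusted over the list alone, and Atp5b (−0.21), Atp5j (−0.22) and Atp5j2 (−0.18) were among those with the smallest p. The 17 class I genes had a median of 0.203 (adjusted p = 0.0147, 8.54e-05 with the block, and adjusted p = 0.95 and 0.903 with an estimated correlation). With the block 2 of them rose, and 4 did so adjusted over the list alone. H2-Q7, one of a family of similar genes (chromosome 17, 35439155 to 35443773), rose from 134 ± 43.02 to 251 ± 154 CPM (SD, n = 3 each, paired log2 0.795, SE 0.13, adjusted p = 0.0292), while H2-T22 (0.36), H2-T23 (0.39) and the immunoproteasome gene Psmb8 (0.198) passed in neither fit. The 26 interferon genes had a median of 0.168 (adjusted p = 0.00697, 0.00114 with the block, and adjusted p = 0.95 and 0.903 with an estimated correlation). With the block 2 rose, Zbp1 among them, and 2 did so adjusted over the list alone, while the interferon regulator gene Irf7 (0.81, adjusted p = 0.772), Ifi27l2a (0.503) and Ifit3 (0.51) passed in neither fit. Of 16 coagulation genes 14 were measured, with a median of 0.206 (adjusted p = 0.0147, 4.59e-04 with the block, and adjusted p = 0.807 and 0.596 with an estimated correlation). With the block 1 of them rose and 4 did so adjusted over the list alone. The P-selectin gene Selp (1.05, adjusted p = 0.838), the urokinase gene Plau (1.12, 0.934) and S100a10 (−0.23, 0.999) did not pass without the block. The interferon list had an adjusted p of 0.0725 without young replicate 2, 0.974 without aged replicate 1, with the opposite direction, and 0.893 without replicate 1 in the blocked fit. Class I had 0.239 without young replicate 3, 0.826 without aged replicate 1, with the opposite direction, and 0.104 without replicate 1 in the blocked fit, and coagulation 0.162, 0.226 and 0.278 without young replicate 3 and aged replicates 1 and 2. In capillary-like cells alone the interferon, class I and coagulation lists had an adjusted p of 0.248, 0.0616 and 0.842 without the block. With it they had 0.0272, 1.46e-05 and 0.731, so that the block called the interferon and class I lists higher there (adjusted p = 0.736 and 0.703 with an estimated correlation). Without the block the highest over all alternatives was 0.98, 0.98 and 0.98. In these endothelial cells platelet markers summed to 28.4 CPM in young and 51.5 in aged libraries, and macrophage markers to 6.01 and 15.1. Whether RNA of such cells moved the 3 lists was not tested.

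Fatty acid handling genes were called lower as a list in all endothelial cells with the block and not without it. The 20 of 23 genes measured had a median log2 fold change of −0.012 and a mean of −0.107 (adjusted p = 0.0766, 0.0178 with the block, and adjusted p = 0.807 and 0.596 with an estimated correlation). With the block 1 gene fell, Timp4, which encodes an inhibitor of metalloproteinases, and 4 did so adjusted over the list alone. The glycerol channel gene Aqp7 was at 706 ± 194 and 523 ± 90.5 CPM (SD, n = 3 each, log2 −0.43, adjusted p = 0.999), the fatty acid binding gene Fabp5 at a log2 of −0.36 and the transcription factor gene Meox2 at −0.23. The blocked call was lost without replicate 2 (adjusted p = 0.0591) and in capillary-like cells alone (0.0627, highest 0.596). The list passed without the block when young replicate 1 (0.0265) or aged replicate 3 (0.0112) was left out, with a highest value of 0.807.

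Lists of leukocyte adhesion, TGFβ signalling, matrix and nitric oxide genes did not pass as lists in all endothelial cells, while single members did with the block. In the leukocyte adhesion list (16 measured, median log2 0.06, camera adjusted p = 0.234 and 0.105 with the block) 3 genes rose with the block. The E-selectin gene Sele rose from 1.84 ± 0.84 to 6.87 ± 1.5 CPM (SD, n = 3 each, paired log2 1.79, adjusted p = 0.0346) and the chemokine gene Cx3cl1 from 29.8 ± 1.83 to 46.4 ± 8.14 (0.601, 0.0463), and Cxcl9 was at a log2 of −0.37. Adjusted over the list alone, 6 rose and 1 fell with the block, and 3 and 1 without it. In the TGFβ and mesenchymal transition list (median 0.064, adjusted p = 0.624 and 0.13) the calcium-binding S100a6 rose with the block from 280.2 ± 71.1 to 539.7 ± 86.3 CPM (0.95, 0.00559). The inhibitory Smad6 rose from 70.2 ± 18.1 to 110.1 ± 23.95 (0.66, 0.00331). In all, 4 genes rose adjusted over the list alone, against 1 without the block. The basement membrane list (median −0.008, adjusted p = 0.472 and 0.985) had 1 gene that rose with the block, the proteoglycan gene Bgn (0.61, 0.0246), with 2 higher and 2 lower adjusted over the list alone. The nitric oxide list (median −0.044, mean 0.09, adjusted p = 0.968 and 0.671) had 2 genes that fell with the block, among them the chaperone gene Hsp90aa1, and 3 higher and 2 lower adjusted over the list alone. The blocked adjusted p was 0.196 and 0.05 without replicates 1 and 2 for Sele, 0.228 and 0.0995 without replicates 1 and 2 for Cx3cl1, 0.131 without replicate 1 for Bgn and 0.0975 without replicate 1 for Hsp90aa1. Over all alternatives the highest was 0.196, 0.267, 0.131 and 0.0975. As lists, leukocyte adhesion passed without young replicate 1 (0.0259), aged replicate 3 (0.00195) or, blocked, replicate 3 (0.00252), basement membrane without young replicate 2 (0.00225) and TGFβ, blocked, without replicate 3 (0.00156), with highest values of 0.98 and 0.903, 0.998, and 0.958.

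In the remaining lists no member passed in all endothelial cells over all genes tested in either fit of edgeR, and members are given as log2 fold changes without the block, with camera's adjusted p without and with it. Senescence and secretory genes had a median of −0.04 and a mean of 0.203 (0.703 and 0.788), with Timp1 at 1.26 and Igfbp7 at −0.29. Immediate early genes had a median of −0.016 (0.45 and 0.236), with Klf6 at −0.39 and Socs3 at 0.44. Unfolded protein response genes had a median of −0.04 (0.234 and 0.13), with Herpud1 at −0.204 and Manf at −0.19. Mitochondrially encoded genes had a median of 0.022 (0.998 and 0.662, the blocked test pointing down), with mt-Atp8 at 0.39 and mt-Co3 at −0.25. Cytosolic ribosomal protein genes had a median of 0.047 (0.234 and 0.105), with Rps28 at 0.395 and Rps29 at 0.29. Glycolysis genes had a median of 0.056 (0.624 and 0.338), with Aldoa at 0.26 and Pgk1 at −0.75. VEGF and angiogenesis genes had a median of 0.103 with the unblocked test pointing down (0.988 and 0.788), with Vegfa at 0.98 and Aplnr at −0.62. Notch genes had a median of 0.099 with the unblocked test pointing down (0.998 and 0.879), with Lfng at −0.46 and Hey1 at 0.295. Junction genes had a median of −0.012 and a mean of 0.004 (0.74 and 0.689), with Jam3 at −0.29 and Gja5 at 0.33. Antioxidant genes had a median of −0.051 and a mean of 0.085 (0.775 and 0.808), with Mt1 at 0.89 and Hmox1 at −0.36. Cell cycle genes had a median of −0.097 (0.234 and 0.476), with Ube2c at −0.59 and Ccna2 at −0.38. Autophagy and lysosome genes had a median of −0.054 (0.533 and 0.476), with Atg7 at −0.47 and Ctsd at 0.15. Sirtuin and DNA maintenance genes had a median of 0.052 (0.234 and 0.257), with Sirt6 at 0.82 and Foxo3 at 0.39. Adjusted over the list alone with the block, 1 gene rose in each of the senescence, immediate early, VEGF and antioxidant lists and 1 fell in each of the senescence, immediate early, VEGF and Notch lists. The ribosomal list passed as higher without young replicates 1 and 3 and aged replicate 2 (adjusted p = 0.00458, 0.00216 and 1.38e-12) and as lower without young replicate 2 and aged replicate 1 (0.0172 and 0.00215), against a highest value of 0.98 over its alternatives. It passed in the blocked fit without replicate 2 (4.78e-05, highest 0.929). The mitochondrially encoded list passed in the blocked fit as higher without replicate 2 and as lower without replicate 3 (0.0308 and 7.37e-04, highest 0.929). Without the block, leaving out 1 library also passed the immediate early list (young replicate 3, 0.00527, and aged replicate 1, 5.48e-05), the unfolded protein response list (aged replicate 2, 0.0109) and the cell cycle and glycolysis lists (aged replicate 3, 0.0116 and 0.0071). In the blocked fit it passed the immediate early list (replicate 1, 5.70e-06), the unfolded protein response and cell cycle lists (replicate 2, 7.29e-04 and 0.0328) and the glycolysis list (replicate 3, 0.00672). In capillary-like cells alone the blocked fit called the immediate early and unfolded protein response lists lower (adjusted p = 0.0136 and 0.0272, and adjusted p = 0.703 and 0.703 with an estimated correlation). The highest value over the alternatives was 0.98 without and 0.929 with the block for each of these 4 lists.

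Capillary-like cells of aged hearts held more RNA of Csprs, Klra9, Aspa and S100a6 and less of Akap5. Csprs rose from 9.01 ± 2.05 to 83.8 ± 33.8 CPM (SD, n = 3 each, log2 3.16, SE 0.33, adjusted p = 0.00403) and Klra9 from 58.6 ± 5.5 to 168 ± 31.6 (1.51, SE 0.17, 0.00403). Aspa, which encodes aspartoacylase, rose from 15.1 ± 3.03 to 43.1 ± 7.72 (1.51, SE 0.21, 0.0177) and S100a6 from 153 ± 46.7 to 400.3 ± 59.3 (1.38, SE 0.2, 0.0241). Akap5, which encodes a kinase anchoring protein, fell from 33.1 ± 3.08 to 13.7 ± 1.62 CPM (−1.26, SE 0.201, 0.0333). With the block, Ubd (4.42, 2.24e-05), Mnda (1.84, 0.0117) and Uchl1 (1.68, 5.68e-04) rose and Stxbp6 (−1.24, 7.75e-04), Lfng (−0.99, 0.0117) and Chst7 (−0.84, 0.0143) fell. The edgeR test called 7 genes higher and 1 lower of 9668, and 55 and 26 with the block, and the groups did not overlap for 9.46% of genes (chance 10%). The count was 2, 3, 4, 2 and 3 without young replicates 1, 2 and 3 and aged replicates 1 and 3, and the blocked count 164 without replicate 2. The adjusted p was 0.175 without young replicate 2 for Csprs and 0.0949, 0.191, 0.0798 and 0.103 without young replicates 1 and 3 and aged replicates 1 and 3 for Aspa. It was 0.0949, 0.117, 0.124 and 0.105 without young replicates 1 and 2 and aged replicates 1 and 3 for S100a6 and 0.0927 to 0.212 without any 1 library for Akap5, with highest values over all alternatives of 0.175, 0.191, 0.124 and 0.373. In the fits without 1 library just named the log2 fold change was 3.13 for Csprs and 1.41 to 1.46 for Aspa. It was 1.24 to 1.33 for S100a6 and −1.17 to −1.39 for Akap5. With the block the adjusted p was 0.0567 without replicate 3 for Stxbp6, 0.0515 without replicate 1 for Lfng and 0.413 without replicate 3 for Chst7, with highest values of 0.0711, 0.426 and 0.693. The blocked call of Uchl1 was lost with totals thinned to the smallest library (adjusted p = 0.2, the highest over its alternatives).

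In arterial-like cells of aged hearts 5 of 6 measured class II genes rose without the block and 6 with it, as 6 did adjusted over the list alone. H2-DMb1 rose from 8.12 ± 3.83 to 50.2 ± 13.6 CPM (SD, n = 3 each, log2 2.4, SE 0.34, adjusted p = 0.0123). H2-Aa rose from 19.6 ± 10.7 to 109 ± 39.6 (2.28, SE 0.34, 0.0211) and H2-DMa from 5.33 ± 1.33 to 30.7 ± 14.1 (2.17, SE 0.396, 0.043). Csprs rose from 5.54 ± 2.99 to 79.9 ± 49.4 CPM (3.72, SE 0.52, 0.0211). With the block, Cd74 rose from 48.3 ± 35.1 to 294 ± 142 CPM (2.58, 2.14e-10) and Zbp1 also rose (2.96, 0.00133). The xenobiotic-metabolising gene Cyp1a1 fell with the block from 47.5 ± 34.4 to 10.8 ± 5.09 CPM (−2.45, 6.89e-06), as did Rsrp1 (−1.14, 3.63e-07), Hspa1a (−0.94, 2.85e-06) and Hspa1b (−0.85, 0.0161). In the same cells 6 of 20 immediate early genes fell with the block and 12 did so adjusted over the list alone. Camera called that list lower (median log2 −0.422, adjusted p = 1.63e-10, and 1.89e-19 with the block). That call was lost with an estimated correlation (adjusted p = 0.494 and 0.313). Without the block, edgeR called 10 genes higher and 0 lower of 7805, and DESeq2 called 12 higher and 1 lower. By edgeR without the block, 276 had an unadjusted p under 0.05, fewer than chance alone would give. The blocked test called 44 and 24, and the groups did not overlap for 8.64% of genes (chance 10%). The unblocked count was 6, 4, 0, 5, 2 and 3 without young replicates 1, 2 and 3 and aged replicates 1, 2 and 3. The adjusted p was 0.24, 0.165 and 0.18 without young replicates 2 and 3 and aged replicate 2 for Csprs and 0.15 without young replicate 3 for H2-DMb1. It was 0.165, 0.18 and 0.0634 without young replicate 3 and aged replicates 2 and 3 for H2-Aa and 0.0948 to 0.286 without any 1 library for H2-DMa, and 0.154 without replicate 2 for Hspa1b with the block. The highest over all alternatives was 0.24, 0.15, 0.18, 0.286 and 0.584.

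In venous-like cells 3 Serpina1 genes rose. Serpina1e went from 31.5 ± 12.2 to 334 ± 120.2 CPM (SD, n = 3 each, log2 3.32, SE 0.33), Serpina1d from 14.2 ± 4.1 to 147 ± 16.3 (3.24, SE 0.33) and Serpina1b from 22.4 ± 3.89 to 197 ± 47.97 (3.04, SE 0.31), each with an adjusted p of 7.78e-06. With the block, Cd74 rose from 48.1 ± 41 to 452 ± 562 CPM (3.096, 4.15e-10), with 1100.5 CPM in aged replicate 1 against 156 and 99.1 in aged replicates 2 and 3, and the paired log2 change was 2.39 without pair 1. Also with the block, Rgs5 (−2.24, 0.00937), Timp4 (−0.95, 0.00117), Rhob (−0.89, 0.0474) and Cdkn1c (−0.87, 0.0214) fell. As3mt (log2 1.16, adjusted p = 0.951), Dusp6 (−0.94, 1) and Igf2bp3 (−1.39, 1) did not pass without the block. The edgeR test called 3 genes higher and 0 lower of 4994, and DESeq2 called 3 higher and 0 lower. By edgeR without the block, 158 had an unadjusted p under 0.05, fewer than chance alone would give. The blocked test called 11 and 9, and the groups did not overlap for 9.25% of genes (chance 10%). The blocked count was 45 without replicate 1, and the blocked adjusted p was 0.523 without replicate 2 for Rgs5, 0.523 and 0.175 without replicates 2 and 3 for Rhob and 0.577 without replicate 3 for Cdkn1c, with highest values over all alternatives of 0.523, 1 and 0.985. The blocked call of Timp4 was lost with equal cell numbers (adjusted p = 0.553, the highest over its alternatives).

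In endocardial-like cells the class I genes H2-Q6 and H2-Q7, members of a family of similar genes, rose with the block. H2-Q6 went from 17.6 ± 16.7 to 96.8 ± 115 CPM (SD, n = 3 each, paired log2 2.56, SE 0.37, adjusted p = 5.53e-04) and H2-Q7 from 64.7 ± 35.7 to 197 ± 159 (1.64, SE 0.23, 3.23e-04). Aged replicate 1 stood apart in both, at 229 CPM of H2-Q6 against 19.8 and 41.4 in aged replicates 2 and 3, and at 380.3 CPM of H2-Q7 against 106 and 105. Tnfaip2 (1.71, 0.0194) and the transcription factor gene Sox18 (1.18, 0.00814) rose as well, and Bambi, which encodes a decoy receptor for TGFβ signals (−1.03, 0.0351), Tsc22d3 (−0.97, 0.00814) and Tmem158 (−0.84, 0.0311) fell. Without the block, Pla2g16 (0.96), Cystm1 (0.77), Nr4a2 (−1.26) and Rxrb (−1.81) did not pass. The unblocked edgeR test called 0 of 5253 genes, with 152 at an unadjusted p under 0.05, fewer than chance alone would give, and 0 calls by DESeq2. The blocked test called 8 higher and 4 lower, DESeq2's blocked test 0 (57 at an unadjusted p under 0.05), and the groups did not overlap for 7.88% of genes (chance 10%). The unblocked count was 1 and 4 without aged replicates 1 and 2, and the blocked count 2, 44 and 0 without replicates 1, 2 and 3. The blocked adjusted p was 0.138 and 0.242 without replicates 1 and 3 for H2-Q7, 0.452 and 0.597 without replicates 1 and 3 for Tnfaip2 and 0.229 and 0.517 without replicates 1 and 3 for Sox18. It was 0.244, 0.142 and 0.4 without replicates 1, 2 and 3 for Bambi, 0.0557, 0.098 and 0.242 without replicates 1, 2 and 3 for Tsc22d3 and 0.138 and 0.608 without replicates 1 and 3 for Tmem158, while H2-Q6 fell under the count filter, and was not tested, without replicates 1 and 3. The highest over all alternatives was 0.946, 0.333, 1, 1, 1, 1 and 1 for H2-Q6, H2-Q7, Tnfaip2, Sox18, Bambi, Tsc22d3 and Tmem158.

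In lymphatic-like cells, of which each library held 41, 40, 63, 44, 32 and 92 in the order young 1 to 3 and aged 1 to 3, H2-Q7, B2m and Pam rose and Cldn11 fell. H2-Q7 went from 14.7 ± 25.5 to 265 ± 39.5 CPM (SD, n = 3 each, log2 4.07, SE 0.67, adjusted p = 0.0015), with 0, 0 and 44.2 CPM in young replicates 1, 2 and 3. Without young replicate 3 the fitted log2 fold change of H2-Q7 in lymphatic-like cells was 7.28, against young libraries at 0. B2m, which encodes the light chain of class I molecules, went from 1804 ± 213 to 4363 ± 868 (1.27, SE 0.27, 0.0249). Pam went from 267 ± 66.01 to 629 ± 92.5 (1.19, SE 0.28, 0.0477). The tight junction gene Cldn11 went from 354 ± 82.1 to 102 ± 21.7 CPM (−1.73, SE 0.34, 0.0128). With the block, Socs3 (1.299, 5.74e-05) and Apoe (1.26, 0.00589) rose and Adm (−1.26, 3.97e-05), Psmd7 (−1.198, 0.0463) and Anxa1 (−1.11, 0.0282) fell. The edgeR test called 5 genes higher and 1 lower of 1657, 13 and 5 with the block, and the groups did not overlap for 9.47% of genes (chance 10%). The count was 2, 2, 2, 3 and 2 without young replicates 1, 2 and 3 and aged replicates 2 and 3. Without replicate 1 the blocked count was 0 (101 at an unadjusted p under 0.05), so that no gene kept its blocked call. The blocked adjusted p was 0.602 without replicate 1 for Socs3 and 0.721 and 0.95 without replicates 1 and 2 for Apoe. It was 0.602 without replicate 1 for Adm, 0.698, 0.144 and 0.185 without replicates 1, 2 and 3 for Psmd7 and 0.666, 0.23 and 0.185 without replicates 1, 2 and 3 for Anxa1. The highest values were 0.602, 1, 0.602, 1 and 1. The adjusted p was 0.0771 without aged replicate 3 for H2-Q7. It was 0.148, 0.441, 0.172, 0.0679 and 0.0521 without young replicates 1, 2 and 3 and aged replicates 1 and 3 for B2m, 0.0671 to 0.475 without any 1 library for Pam and 0.148, 0.0798 and 0.0771 without young replicate 1 and aged replicates 2 and 3 for Cldn11. The highest over all alternatives was 0.0771, 0.441, 0.614 and 0.207.

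With the block, H2-Q6, H2-Q7 and S100a6 were called in 4 of the 5 subtypes, and Cd74, H2-Ab1, Hspa1a, Cdkn1c, Rhob, Rsrp1, Sox18 and Tsc22d3 in 3. Whether the age effect differed between subtypes was tested on the difference between a pair of subtypes within each library. No gene passed in any of the 10 pairs by limma (0 calls, with 75 to 392 genes at an unadjusted p under 0.05, and 0 calls with DESeq2's size factors, with 77 to 388). These counts at an unadjusted p are close to what chance alone would give for the genes tested in each pair. Among the genes with the smallest p of a pair were As3mt between capillary- and venous-like cells (difference of log2 changes −1.61, adjusted p = 0.897) and Yod1 between capillary- and endocardial-like (−1.18, adjusted p = 0.832). So were S100a6 between capillary- and lymphatic-like (1.55, adjusted p = 0.275) and Avpi1 between arterial- and venous-like cells (1.66, adjusted p = 0.862). Others were Nr4a2 between arterial- and endocardial-like (1.56, adjusted p = 0.804) and Cd24a between arterial- and lymphatic-like (1.65, adjusted p = 0.203). So were Yod1 between venous- and endocardial-like (−2.001, adjusted p = 0.885) and Sap18 between venous- and lymphatic-like cells (−1.19, adjusted p = 0.806). On simulated counts for capillary against arterial cells this test found 7% of genes whose change differed 2-fold and 74% of those that differed 4-fold.

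Cell-to-cell variability was measured in capillary-like cells. The median of 1 minus the Spearman correlation of a cell to the mean profile of its library was 0.694 ± 0.00391 in young and 0.698 ± 0.00277 in aged libraries (SD, n = 3 each, 323 cells per library thinned to 1000 UMIs, exact two-sided permutation test, p = 0.3). With cells thinned to 2000 UMIs it was 0.612 ± 0.00352 and 0.615 ± 0.00564 (exact p = 0.4), so the measure moved more with the UMIs kept per cell than between the age groups. Neither of these tests can give a p under 0.1. In both settings the value was higher in the aged library of 3 of 3 pairs of equal replicate number (mean difference 0.00378 at 1000 UMIs, exact sign-flip p = 0.25, the smallest that 3 pairs can give). None of these tests shows that variability was alike.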

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

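Tests added after the result was seen are the alternatives of the blocked fits, the removal of expected doublets, the paired test of variability and the clusterings with the Cytl1-led cluster named or without called genes. Of the single genes' values, 2452 kept direction and side of the threshold, 96 lost and 63 gained the call and 11 changed sign, and with the block 779 kept both, 148 lost and 3 gained the call. The 2452 include values of genes not called to begin with, which cannot lose a call, so they do not measure how firm the calls were. Without the block the call was lost in 14 of 16 settings for Pam in lymphatic-like cells. In all endothelial cells it was lost in 10 of 19 for Cystm1 and 0 of 19 for Serpina1d. Counts of called genes, given first for all endothelial, then capillary-, arterial-, venous-, endocardial- and lymphatic-like cells, were 7, 8, 10, 3, 0 and 6, and 109, 81, 68, 20, 12 and 18 with the replicate number as a block. Without a filter on low counts they were 22, 42, 44, 13, 4 and 12, and 459, 216, 122, 43 and 40 with the block in all but lymphatic-like cells. Drawing equal cell numbers gave 3, 5, 3, 0 and 3 in all endothelial, capillary-, arterial-, venous- and lymphatic-like cells, and 53, 44, 36, 4, 4 and 9 blocked. DESeq2's Wald test gave 34, 24 and 3 in all endothelial, capillary- and lymphatic-like cells, and 66, 36, 27, 9, 0 and 2 blocked (57 endocardial genes at an unadjusted p under 0.05). Totals thinned to the smallest library gave 4, 2 and 0 in capillary-, arterial- and lymphatic-like cells, and 41, 33, 12 and 1 blocked in capillary-, arterial-, venous- and endocardial-like cells. A CPM of at least 10 in 3 libraries gave 4 in all endothelial and 19 in lymphatic-like cells, and 49 blocked in venous-like cells. Stricter cell filters gave 4 and 3 in all endothelial and lymphatic-like cells, and the capillary share as a covariate gave 19 in all endothelial cells. Keeping the doublets Scrublet called, a setting in which the cells were clustered anew so that class membership changed as well, gave 3 in lymphatic-like cells and, blocked, 139, 57 and 6 in arterial-, venous- and endocardial-like cells. Removing the expected doublets gave 5 in arterial-like and, blocked, 4 in endocardial-like cells, naming the Cytl1-led cluster gave 5 in the latter, and DESeq2's size factors gave 3 in lymphatic-like cells (2 higher and 1 lower, against 5 and 1). Leaving out 1 library gave 2 to 6, 2 to 10, 0 to 6, 3 to 4, 0 to 4 and 2 to 6, and leaving out 1 pair in the blocked fit gave 51 to 228, 78 to 164, 54 to 97, 18 to 45, 0 to 44 and 0 to 17. Of the gene lists 6 were called, and 7 with the block, against 0 in either with an estimated correlation, 0 in either with fry, 3 in capillary-like cells alone without the block, 5 to 10 without 1 library and 6 to 11 without 1 pair. Leaving out 1 library, the adjusted p of the list type I interferon response ranged over 4.33e-07 to 0.974, the adjusted p of the list MHC class I presentation over 4.57e-06 to 0.826 and the adjusted p of the list cytosolic ribosomal proteins over 1.38e-12 to 0.971, each with changes of direction. Without 1 pair, the adjusted p of the list mitochondrially encoded, paired by replicate number, ranged, with a change of direction, over 7.37e-04 to 0.511. Among genes that did not pass, the log2 fold change of Lcp1 in all endothelial cells was 0.18 when all barcodes were summed, the log2 fold change of Atg5 in all endothelial cells 0.020 with equal cell numbers, and the log2 fold change of Ddx3y in all endothelial cells −0.068 with thinned totals and −0.070 to 0.21 without 1 library. Without 1 library the log2 fold change of Pdpn in all endothelial cells ranged over −0.24 to 0.81, the log2 fold change of Cdh5 in all endothelial cells over −0.1025 to 0.015, and the log2 fold change of Dusp1 in all endothelial cells over −0.48 to 0.0000834. So did the log2 fold change of Manf in all endothelial cells over −0.31 to 0.0054 and the log2 fold change of Gabarapl1 in all endothelial cells over −0.00023 to 0.56. The difference in share, aged minus young, of capillary-like cells was 0.609 percentage points with stricter cell filters and −1.59 to 1.26 without 1 library, that of lymphatic-like cells −0.0156 to 1.46 without 1 library, and that of unnamed clusters −1.36 with the Cytl1-led cluster named and −0.461 to 2.56 without 1 library. The capillary difference, −0.528 points as reported, was −6.17 without centring within libraries, and −4.89 and −1.98 at clustering resolutions 0.6 and 1.5. The angiogenic difference, −2.33 as reported, was −0.228, −0.031 and −1.44 in these settings. Without centring the interferon difference was 1.63 against 0.513 and the arterial −1.68 against −2.81. With Scrublet's doublets kept the capillary, arterial and venous differences were −1.47, −1.62 and −0.573, against −0.999 for the venous as reported. At resolution 0.6 that of unnamed clusters was 2.74 against 1.41, and 0.911 at resolution 1.5. The endocardial difference, 3.42 as reported, was 6.19 with the Cytl1-led cluster named. The difference in median genes per cell was −73 as deposited and 0.667 after thinning to 1000 UMIs, which removes the depth difference by construction. For all these changes the cause was not tested, unless the setting itself removes genes, cells or libraries. Beyond the counts and calls printed with it, the replicate block changed no other call among the values printed in the text, while further genes it called in a class are only counted. No venous-like cluster was found without centring within libraries, so that setting gives no venous value. Depth limits the smaller classes most, with 1657 genes tested in lymphatic-like cells.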

Other observations

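Within subtypes, the list of class II presentation genes was higher in aged capillary-, arterial- and venous-like cells. With the replicate number as a block, 2 of 2 measured members rose in capillary-like, 6 of 6 in arterial-like and 3 of 3 in venous-like cells, and 0 of 1 in endocardial-like cells by edgeR (344 of all endocardial genes at an unadjusted p under 0.05, and 0 calls by DESeq2). The median log2 changes with the block were 2.108, 2.296, 2.017 and 0.6, with camera's adjusted p at 8.40e-06, 9.96e-27, 3.95e-13 and 0.452. These calls were lost with an estimated correlation (adjusted p = 0.448, 0.313 and 0.568 in capillary-, arterial- and venous-like cells). Heat shock genes that fell with the block numbered 6 of 15 in capillary-like, 6 of 14 in arterial-like and 1 of 13 in venous-like cells. By edgeR they numbered 0 of 14 in endocardial-like cells, with the counts at an unadjusted p and by DESeq2 as above, and 0 of 8 in lymphatic-like cells (111 of all lymphatic genes at an unadjusted p under 0.05, and 2 calls by DESeq2). The test of a difference in age effect between subtypes called no gene.

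Further lists passed within a subtype in both fits, by camera with a preset correlation, with the adjusted p given first without and then with the block. In capillary-like cells the heat shock (adjusted p = 1.62e-08 and 1.02e-15) and oxidative phosphorylation (1.33e-06 and 7.42e-10) lists were lower, and in arterial-like cells the heat shock (2.67e-08 and 2.41e-14), oxidative phosphorylation (0.00403 and 4.21e-05) and senescence and secretory (0.00403 and 2.79e-04) lists were lower. In venous-like cells the interferon (0.0153 and 9.42e-05) and class I (0.00995 and 5.24e-07) lists were higher and the heat shock (0.00563 and 9.42e-05) and fatty acid (0.03 and 5.35e-04) lists lower. In endocardial-like cells the interferon (0.00355 and 6.51e-06), class I (0.00355 and 8.08e-08) and ribosomal (0.0124 and 3.65e-05) lists were higher and the heat shock (0.0284 and 0.0105), fatty acid (0.0359 and 4.28e-04) and basement membrane (0.00355 and 3.19e-05) lists lower. In lymphatic-like cells the interferon (3.19e-05 and 7.50e-08) and class I (1.94e-07 and 6.07e-11) lists were higher and the heat shock list lower (0.0376 and 0.00534). With the block, edgeR called 1 of 16, 2 of 16 and 3 of 12 class I genes higher in venous-, endocardial- and lymphatic-like cells, 1 of 7 interferon genes higher in lymphatic-like and 1 of 14 fatty acid genes lower in venous-like cells. It called 0 members of the other lists just named, heat shock apart, where capillary-, arterial-, venous- and endocardial-like cells had 990, 653, 341 and 344 genes in all at an unadjusted p under 0.05 and 36, 27, 9 and 0 calls by DESeq2 with the block. None of these list calls held with an estimated correlation (adjusted p from 0.186 to 0.88 without and 0.313 to 0.789 with the block).

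Other lists passed within a subtype with the block and not without it, by camera with a preset correlation. In arterial-like cells the class I (adjusted p = 0.00676) and ribosomal (0.00146) lists were higher. In venous-like cells the leukocyte adhesion list was higher (0.0269) and oxidative phosphorylation lower (0.0401), while the VEGF list, lower without the block (adjusted p = 0.0226, and adjusted p = 0.772 with an estimated correlation), did not pass with it (0.0766). In endocardial-like cells the leukocyte adhesion (0.0268) and mitochondrially encoded (0.0396) lists were higher and those of junctions (0.0454) and nitric oxide (0.0396) lower. In lymphatic-like cells the leukocyte adhesion (0.0384) and immediate early (1.34e-05) lists were higher. None of these blocked calls held with an estimated correlation (adjusted p from 0.568 to 0.775).

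All tests below were chosen after the result was seen, apart from the test of the Hspa1a-led cluster. Class II genes were higher in aged endothelial cells, and RNA of other cells in the droplets is a technical explanation. The rise of B-cell genes reached at most 8.95% of what the class II rise would need at the ratio seen in B-cell-like cells, and that of macrophage genes at most 8.08%, over the 3 pairs and at the upper bound of the counts, which argues against both. Giving each young library the cluster make-up of its aged partner accounted for at most 15.5% of the log2 rise, which argues against a shift between clusters. RNA of other class II-bearing cells was not tested and stays open. The sort against CD45 did not remove all cells that carry it, since clusters of 158 B-cell-like and 80 macrophage-like cells remained. Also open is an effect of age in endothelial cells, which may account for the rise as an untested hypothesis.

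Heat shock genes were lower in aged cells, which could come from the stressed cells or from handling. Without the cluster led by Hspa1a, 98.7% of the median fall of the list was kept, which argues against a smaller share of that cluster. The median paired log2 change of the immediate early list, which handling would also move, was −0.031, between the bounds set for and against handling. It was −0.124 in capillary-, −0.438 in arterial-, −0.042 in venous-, 0.044 in endocardial- and 0.19 in lymphatic-like cells, of which the arterial value lies past the bound set for handling. Handling thus stays open and cannot be told apart from age, which was not tested, since no handling record was used here.

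Csprs and members of the Serpina1 family were among the largest rises, and reads split between near-identical copies are a technical explanation. The summed CPM of all Serpina1 genes rose by at least 3.31 on the log2 scale in the 3 pairs, which argues against reads moving between the copies. A sequence or copy number difference between the young and the aged mice would raise Csprs alike in all subtypes, and its lowest paired log2 change over the subtypes where it was tested, capillary- and arterial-like cells, was 3.13. That value is consistent with such a difference, and it does not separate it from an effect of age, which stays open and untested.

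Libraries in groups of 3 against 3 make 10 splits, of which 4 part all 3 pairs, too few for a share under 0.05. The splits with a count as large, the real one included, and the highest count of the others were 1 of 10 splits and 0 for the 7 genes of all endothelial cells, 1 of 10 splits and 0 for the 8 of capillary-like, 1 of 10 splits and 0 for the 10 of arterial-like cells. They were 1 of 10 splits and 1 for the 3 of venous-like, 10 of 10 splits and 3 for the 0 of endocardial-like and 1 of 10 splits and 2 for the 6 of lymphatic-like cells. With the block they were, in the same order, 1 of 4 splits and 0 for 109 genes, 1 of 4 splits and 2 for 81, 1 of 4 splits and 0 for 68, 1 of 4 splits and 1 for 20, 1 of 4 splits and 3 for 12 and 1 of 4 splits and 5 for 18. For the lists they were 9 of 10 splits and 11 for the real 6, and 4 of 4 splits and 8 for the real 7 with the block. So most splits called at least as many lists with the preset correlation as the split by age did. For the difference between subtypes by limma (75 to 392 genes per pair at an unadjusted p under 0.05, and 0 calls with DESeq2's size factors) they were 10 of 10 splits and 0 for the real 0. Unlike the real split, the other splits that part all 3 pairs put libraries of both ages in each group.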
